A study of Mangifera indica with 2 samples.

How the data were processed

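Poly(A)-selected RNA from mango (Mangifera indica) was sequenced from 1 library of tender leaf and 1 library of mature fruit, on an Illumina instrument, per the labels' protocols. The RNA was treated with DNase, selected with oligo(dT) beads, fragmented and copied with random hexamers; no molecular identifiers and no strand marking are described, so reads of a gene and an overlapping antisense transcript cannot be told apart. The protocol also names flower as a source of RNA; flower is not analysed here.

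Bowtie2, a short-read aligner, and RSEM, which assigns reads to transcripts and shares reads that fit several of them, are named in the submitters' processing notes. Their versions, the assembler, the reference sequences and whether read pairs were used are not given in the sources used here. Each file lists the same 99328 genes, each with the names of its transcripts. The IDs carry a component number and a graph number, a form written by de novo transcript assemblers, and they are called assembled genes here.

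The deposited expected counts are RSEM's estimated counts per gene and are not normalized. They were rounded to whole numbers. Estimates were whole within 0.005 for 91.5% of genes in leaf and 91.3% in fruit. Genes with estimates that were not whole held 75.2% of the leaf counts and 78.7% of the fruit counts. Most counts thus lie in genes with at least 1 read shared with other genes or with RSEM's background class. Since 1 such read is enough, these values do not give the share of reads that were shared. The deposited FPKM values, scaled to effective length and library size, were proportional to expected count over effective length. The deposited TPM values summed to 999999.56 in leaf and 1000000.66 in fruit and were not used further. Within a library they are proportional to FPKM, but the constant can differ between libraries. Ratios of TPM with a fixed pseudocount could therefore differ from those of FPKM and were not computed. Gene length and effective length are in bases; they differed by at most 91.8 bases in leaf and 95.0 bases in fruit. The length of a gene with several transcripts differed between the files while that of a gene with 1 transcript did not, so it is taken as a mean weighted by transcript abundance.

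The files do not pair the IDs with gene names, and 0 of the 99328 IDs matched the gene IDs, locus tags, symbols or accessions of the 38372 mango genes in the reference table (assembly CATAS_Mindica_2.1). The 32 gene lists fixed before the data were examined, covering allergen families, photosynthesis, ripening and markers of other tissues and organisms, could therefore not be applied. No chromosome position or gene structure is given for the same reason.

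The rounded total was 20592533 counts in leaf and 22824528 in fruit. Libraries were scaled with the TMM method of edgeR (factors 1.08 for leaf and 0.93 for fruit). Relative to totals alone, this moved every leaf-to-fruit log2 ratio by 0.22 towards fruit. A gene entered the comparison with at least 10 counts in at least 1 library. It was called higher in a tissue when the scaled fold was at least 4 and the near bound of its 95% interval was at least 2. The interval is the exact Clopper-Pearson interval of the gene's leaf share of its counts, turned into a fold. Where a library had 0 counts, the fold was computed against 3 counts in that library and is a lower bound at that limit. The near bound of the 95% interval, used for the calls and the ranking, allows slightly more counts and lies lower; 3 counts correspond to 0.146 CPM (counts per 1000000 counts of the library) in leaf and 0.131 in fruit. Intervals and limits cover counting error only and treat counts as independent. Reads copied by PCR are not independent molecules, and reads shared by RSEM are not whole counts, so the intervals can be too narrow. With 1 library per tissue there is no estimate of the spread between plants or preparations, no p-value was computed, and each call compares these 2 libraries.

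The rule was tested on simulated data: Poisson counts for the real genes at their mean level, with 100 genes changed 8-fold and 100 changed 16-fold. All 100 of the 8-fold and 100 of the 16-fold genes were called in the right direction, and 3 of 35356 unchanged genes were called. These simulated counts hold no variation beyond counting. No changed gene was simulated below 8-fold, so recovery near the 4-fold cut was not tested. Recovery was also not split by count. It therefore does not show how the rule performs at under 50 counts in the higher library, where 1305 leaf and 3205 fruit calls lie.

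The rule for single genes, set before the data were examined, was to name the 2 genes in each direction with the highest near bound of the fold. CPM values use each library's total, without the TMM factor. Medians of log2 ratios and the plotted ratios use a prior count of 0.5. Alternatives were DESeq2 size factors (1 for both libraries, so no scaling), totals with and without the most abundant genes, other count minimums and folds, a length minimum of 500 bases, and FPKM with pseudocounts of 0.1 and 1. Software was R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0 (size factors only), Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.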

Results

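Messenger RNA abundance was measured by RNA sequencing in mango, a tropical fruit tree of the cashew family, in 1 library of tender leaf and 1 library of mature fruit. The series was set up to find transcripts of putative allergens in these tissues. Leaf gave 20592533 counts and fruit 22824528 counts over 99328 assembled genes. There were no replicates, so the intervals below cover counting error only and not the spread between plants or preparations. The genes are known by assembly ID alone, and no allergen family or pathway was scored.

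Many of the assembled genes had reads in each tissue, and fruit held more of them at low level. The reads that the assembly was built from are not given in the sources used here, so the numbers describe these libraries against this assembly. At least 10 counts were found for 30269 genes in leaf and 33237 genes in fruit. With fruit thinned to the leaf total, 32022 fruit genes still reached 10 counts. At 50 counts or more the numbers were close, with 18525 genes in leaf and 18650 in fruit. A further 8568 genes had 0 counts in both libraries. Genes with at least 10 counts in either library had a median length of 817 bases, against 223 bases for the genes at 0 in both.

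The fruit library was concentrated in fewer genes than the leaf library. The 10 most abundant genes held 5.94% of fruit counts (95% Clopper-Pearson interval 5.93 to 5.95%) and 3.77% of leaf counts (3.76 to 3.78%). The single most abundant gene held 1.48% of fruit counts and 0.790% of leaf counts. The 100 most abundant genes held 19.3% of fruit counts and 13.0% of leaf counts. In fruit, 1293 genes were enough to hold 50% of the counts, and in leaf 1647 genes.

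The most abundant genes differed between the tissues. Of the 10 most abundant genes of each library, 1 was shared. Of the 100 most abundant, 26 were shared, and of the 1000 most abundant, 504. Across the 38400 genes with at least 10 counts in either library, Spearman's rho between leaf and fruit was 0.70. This correlation is across genes, which are not independent replicates.

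The main comparison asked which genes were more abundant in leaf and which in fruit. By the rule of a 4-fold difference, 3760 genes were higher in leaf and 6483 genes were higher in fruit, together 26.7% of the 38400 genes compared. The other 28157 genes did not meet the rule, and 18521 genes lay within 2-fold. The genes higher in leaf held 13.4% of leaf counts and 1.08% of fruit counts. The genes higher in fruit held 28.5% of fruit counts and 2.45% of leaf counts. Differences were often large: 1401 of the leaf genes and 2253 of the fruit genes reached 16-fold, and 405 and 606 reached 64-fold.

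The 2 groups were alike in median length but not in depth. The genes higher in leaf had a median length of 791 bases (quartiles 504 and 1328) and those higher in fruit 789 bases (quartiles 549 and 1223). In the tissue where it was higher, the median gene had 96 counts in the leaf group and 51 in the fruit group. The excess of fruit over leaf genes was found mainly at low counts. Among genes with at least 10 and under 50 counts in the higher library, 1305 were higher in leaf and 3205 in fruit. Among genes with at least 200 and under 1000 counts the numbers were 827 and 832, and among genes with 1000 counts or more they were 532 and 896. Scaling to total counts alone gave 4359 genes higher in leaf and 5586 in fruit. On FPKM with a pseudocount of 1, without the interval, the numbers were nearly even, with 2534 genes higher in leaf and 2691 in fruit.

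**Figure D1:**
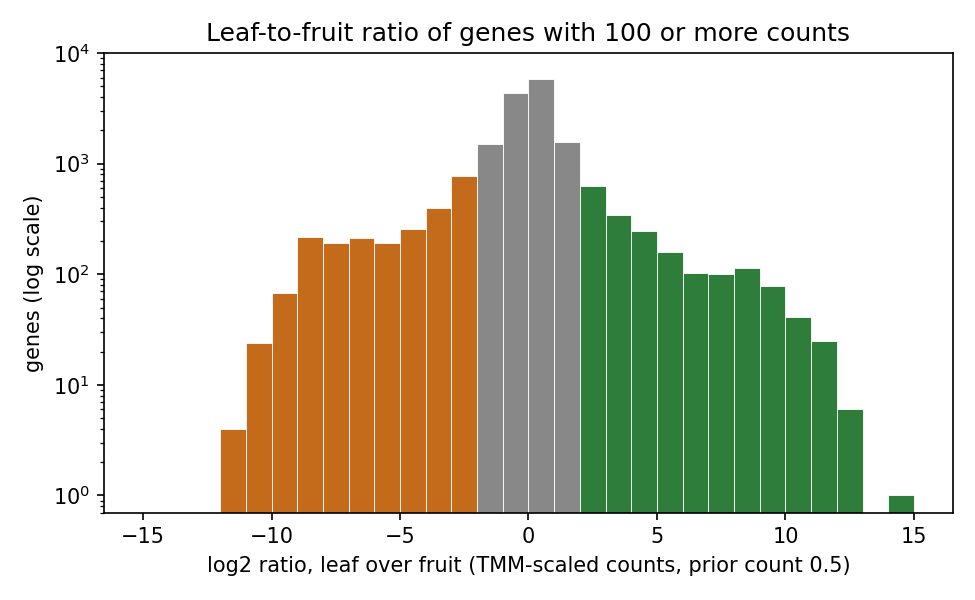
Histogram of the log2 ratio of leaf over fruit (x axis, TMM-scaled counts with a prior count of 0.5) for the 17456 genes with at least 100 counts in either library; the y axis is the number of genes on a log scale. Green bars are ratios of 4-fold or more towards leaf, orange bars 4-fold or more towards fruit and grey bars ratios in between; the 2 bars next to 0 hold 4328 and 5868 genes, and both flanks reach beyond 10 on the log2 scale, where the length of the flank depends on the prior count.

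Among the genes that stood furthest apart, c64822.graph_c0 had 10284 counts in leaf (499 CPM) and 0 counts in fruit. Against 3 counts, the limit set for a count of 0, it was at least 3268-fold higher in leaf, and the near bound of its 95% interval, which allows more than 3 counts, was 2657. The second leaf gene, c64821.graph_c0, had 13043 counts in leaf and 2 in fruit, a ratio of 6217 (95% counting interval 1721 to 51343). In the other direction, c60031.graph_c0 had 48551 counts in fruit (2127 CPM) and 45 in leaf, a ratio of 1132 (846 to 1552), and ranked 25 among the fruit genes. The second fruit gene, c58411.graph_c0, had 7936 counts in fruit and 4 in leaf, a ratio of 2081 (812 to 7640). Each of these 4 genes had a single assembled transcript, with a length of 1301, 1404, 3162 and 1257 bases in the order given. RSEM's estimate was not whole in the higher library for any of the 4 (10284.47, 13043.32, 48550.59 and 7935.96). At least 1 read of each was therefore not assigned to it alone, and the share of such reads is not known.

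A set of genes was seen in one tissue and had a count of 0 in the other. A 0 here is a rounded estimate, so a fraction of a read can lie behind it. With at least 10 counts in one library and 0 in the other, there were 1256 leaf genes and 3658 fruit genes. These genes were mostly weakly expressed: their median was 24 counts in leaf and 20 counts in fruit. They held 0.653% of leaf counts (0.650 to 0.657%) and 0.672% of fruit counts (0.669 to 0.675%). The larger number in fruit came from weakly expressed genes. At 100 counts or more there were 235 leaf genes and 309 fruit genes, and at 1000 counts or more there were 26 leaf genes and 4 fruit genes. Carry-over of reads from fruit to leaf, which remains open below, could lower the fruit number at high counts. A count of 0 allows a level of up to 0.146 CPM in leaf and 0.131 in fruit, so absence from a tissue was not shown.

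The share of called genes was lower among genes with many assembled transcripts than among genes with 1 transcript. Intervals here are 95% Clopper-Pearson intervals that treat genes as independent. Among genes with at least 100 counts, 14.3% of the 5666 single-transcript genes were higher in leaf (13.4 to 15.3%) and 16.4% were higher in fruit (15.4 to 17.4%). Among the 2377 genes with 10 to 29 transcripts, 5.72% were higher in leaf (4.82 to 6.73%) and 7.70% in fruit (6.66 to 8.84%). Among the 864 genes with 30 or more transcripts, 19 were higher in leaf and 76 in fruit. Single-transcript genes were also less abundant, so the shares were compared at matched counts. From 100 to under 300 counts, 32.4% of single-transcript genes (30.4 to 34.4%) and 23.1% of genes with 5 or more transcripts (20.6 to 25.7%) were called in either direction. At 3000 counts or more, these shares were 46.5% (42.3 to 50.6%) and 18.6% (16.1 to 21.4%).

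**Figure D2:**
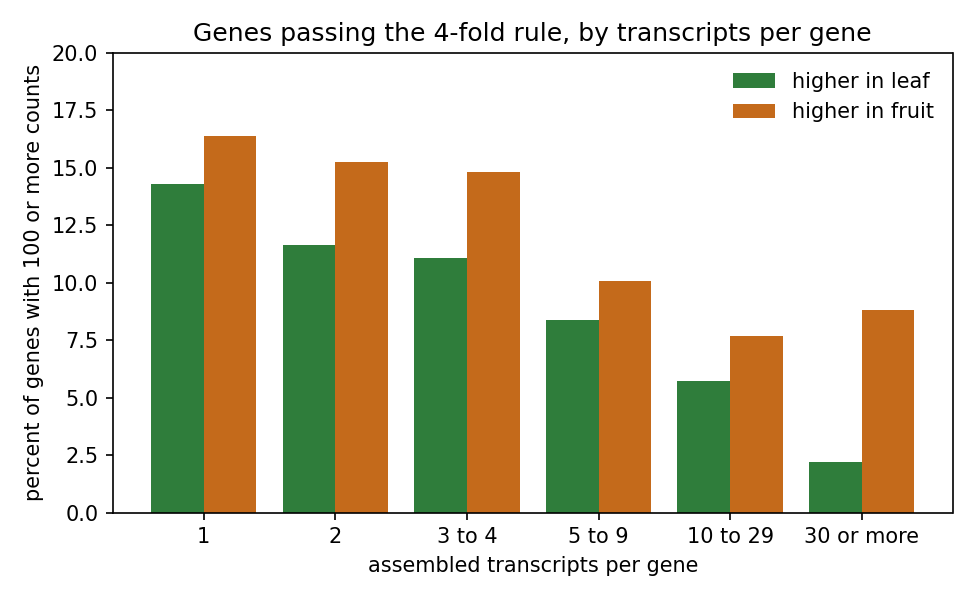
Percent of genes with at least 100 counts (y axis) that were at least 4-fold higher in leaf (green) or in fruit (orange), by the number of assembled transcripts per gene (x axis); there is 1 library per tissue and no error bar. The leaf share goes from 14.3% at 1 transcript to 2.20% at 30 or more, and the fruit share from 16.4% to 8.80%.

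The share of called genes also varied with gene length. Length, transcript number and counts were linked, so these trends were not separated. Over all compared genes, the median length was 631 bases at 1 transcript and 1941 bases at 30 or more. Genes of 2000 bases or more had a median of 1306 counts in the higher library. Among genes with at least 100 counts, 6.73% of those of 2000 bases or more were higher in leaf and 8.82% in fruit. Among genes of at least 500 and under 1000 bases, 14.3% were higher in leaf and 16.2% in fruit (15.0 to 17.4%). Among the 123 genes under 300 bases, 14.6% were higher in leaf and 23.6% in fruit (16.4 to 32.1%), so these fruit intervals overlapped. Over all compared genes the fruit shares were 21.2% at 500 to under 1000 bases, at a median of 32 counts in the higher library, and 11.1% under 300 bases, at a median of 19 counts. The order of the 2 fruit values thus differed between the count minimums, but at 100 counts it was not settled, as the intervals overlapped. The leaf shares over all compared genes were 10.4% and 9.74%.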

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

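The tests of gene length, of reads outside the most abundant genes, of another organism and of carry-over were chosen after the values were seen.

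The deposited gene lengths of leaf and fruit were set against each other, to find genes whose reads fell on different transcripts in the 2 libraries. Of 9289 genes with several transcripts and at least 100 counts in both libraries, 83 had an abundance-weighted length that differed at least 1.5-fold between leaf and fruit. The longer value was in leaf for 46 genes and in fruit for 37. At 1000 counts or more in both, 24 of 2908 genes differed as much. For 12 of the 83, the ratio of counts and the ratio of FPKM had opposite directions, which follows from the length entering the FPKM. The counting error of these lengths is not known, because counts per transcript were not used here.

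Fruit had 2.91 times as many genes seen in it alone as leaf had. The fruit library was 1.11 times deeper, but with fruit thinned to the leaf total the ratio was still 2.498, so depth was not the whole cause. Fruit over leaf reads outside the 1000 most abundant genes came to 1.004. This argues against a few abundant genes crowding out the rest of the leaf reads. It is not a separate test, because fruit had already been seen to be the more concentrated library. RNA of another organism on the fruit, such as a microbe, remains open: these genes held 0.672% of fruit counts, and their sequences were not used here. The difference between the tissues themselves, and between these single samples, also remains open and untested.

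Of the 135 genes at least 64-fold higher in fruit with at least 1000 fruit counts, 4 had a leaf count of 0 and the others kept some leaf reads. Carry-over of reads between libraries at 1 fixed rate was tested on these 135 genes. Their leaf reads scattered around 1 common share (0.672% of the fruit reads) with a variance 41.3 times the mean, which a single rate does not give; leaf expression of some of these genes gives such scatter, so this speaks only against carry-over as the cause of all their leaf reads. In the other direction, the leaf gene with 10284 counts and none in fruit gave a limit of 0.0292% when taken alone. It was picked as the highest leaf count with 0 in fruit, so the rate may lie higher. From fruit to leaf, carry-over at a rate near the lowest share among 2458 genes with at least 2000 fruit counts, 0.0438%, remains open. That share is the lowest of many and carries counting error, so it is not an upper limit. The highest fruit count with 0 in leaf, 1181, gave a limit of 0.254% when taken alone. Of 2449 genes with at least 2000 leaf counts, 7 had 0 counts in fruit. Of the 2458 genes with at least 2000 fruit counts, 0 had 0 counts in leaf.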

How the results depend on the processing

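No replicate could be left out and no other split of the samples exists, because each tissue has 1 library; this also limits every call to these libraries. The other limit is reads that RSEM did not assign to 1 gene alone: 69.0% of the compared genes had whole estimates in both libraries, and they held 15.0% of leaf and 13.4% of fruit counts. As 1 shared read is enough to make an estimate not whole, this set leans to genes with few counts. Among the genes with whole estimates, in an alternative added after seeing the data, 2844 were higher in leaf and 5125 in fruit. More genes were higher in fruit than in leaf under each of the 11 alternatives. These recount the same 2 libraries, and several take a part of the main calls, so they are not independent of each other. Of the alternatives for the main results, 24 stayed within 1.5 times (or within the interval) and 24 moved. DESeq2's size factor was 1 for both libraries, so that alternative compared the counts without scaling, despite the 1.11 times deeper fruit library. It and the alternatives on totals gave 3954 to 4359 genes higher in leaf and 5586 to 6327 in fruit. Dropping the count minimum changed nothing, since the rule itself calls no gene under 10 counts. Genes higher in leaf numbered 2455 at a count minimum of 50, 7571 at 2-fold and 1984 at 8-fold, and those higher in fruit 3278, 10897 and 3420. The leaf share of calls was 36.7% in the main comparison, 43.8% on total counts, 40.6% with FPKM plus 0.1 (4865 genes higher in leaf and 7112 in fruit) and 48.5% with FPKM plus 1 (2534 and 2691). The FPKM alternatives also leave out TMM scaling and the interval, and the cause was not tested. Detected genes numbered 63864 in leaf and 79013 in fruit at 1 count, and 18525 and 18650 at 50 counts. Genes with a count of 0 in the other library numbered 377 in leaf and 757 in fruit at 50 counts. In alternatives added after seeing the data, they numbered 235 and 309 at 100 counts and 26 and 4 at 1000 counts, so at 1000 counts the order turned. Carry-over from fruit to leaf, left open above, could lower the fruit number. The 10 most abundant genes held 3.79% of leaf and 5.40% of fruit FPKM, and the 100 most abundant 13.0% and 19.3% of counts. Spearman's rho was 0.57 over all genes with any count, 0.84 over genes with 10 counts in both libraries and 0.64 on FPKM. The folds of the 4 named genes stayed within their counting intervals under the other scalings.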

Other observations

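The test in this part was chosen after the values were seen.

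Genes that stood at least 64-fold apart with at least 100 counts numbered 374 towards leaf and 542 towards fruit. The leaf set held 2.81% of leaf counts and 0.00745% of fruit counts. The fruit set held 6.86% of fruit counts and 0.0504% of leaf counts. The fruit set was unevenly spread over the assembly numbering: 224 of its 542 genes (41.3%) had component numbers from 61000 to 64799, against 25 of the 374 leaf genes (6.68%) and 22.7% of all genes with at least 100 counts. In that range the median was 2 transcripts per gene in the fruit set, 3 in the leaf set and 7 for all genes with at least 100 counts. The range was chosen from the data.

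Genes of 1 assembly component tended to lie on the same side. Over 886 components with 2 genes of at least 20 counts, the log2 ratios of the 2 genes had a Pearson correlation of 0.64 (Spearman's rho 0.55), while the highest of 1000 random pairings of the same genes was 0.11. First genes of neighbouring component numbers had a correlation of 0.02 over 20359 pairs. In 147 of 151 components with 2 called genes, both were called in the same direction. A candidate explanation is that pieces or copies of related sequence within a component were counted as separate genes, in which case some calls are not independent; genes of 1 family that are used in the same tissue would give the same pattern, and sequences to separate the 2 were not used here.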
